A study of Mus musculus with 15 samples.

How the data were processed

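RNA was sequenced from a midline piece of the free wall of the left ventricle of male mice killed at 225 days, 7 with chronic kidney disease caused by a Col4a5 mutation and 8 wild type. The study's design text calls the samples biological replicates. Per the labels' protocols, total RNA was purified with TRIzol and columns with DNase, every sample had an RNA integrity number of at least 8, and libraries were made with KAPA RiboErase, a kit that removes ribosomal RNA and keeps transcripts without a poly(A) tail. The labels name the mutation both a knockdown and a knockout, and they name both isoflurane and ketamine with xylazine as the anaesthetic. Neither point could be settled from the values.

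Each deposited table holds a raw count, a CPM and an FPKM value for each of 55487 genes in 1 library. Per the submitters' processing notes, the authors used bcl2fastq, STAR 2.7.9a, Subread and featureCounts 2.0.3 with the genome build GRCm38. The counting options, including strand, are not given in the sources used here, so genes that overlap on either strand are treated as uncertain. The deposited CPM values are counts scaled to the library total, and the deposited FPKM values are CPM per kilobase of exon. Both were recomputed from the deposited counts within a relative tolerance of 1e-06 and were not used further. Gene symbols, types and positions came from GENCODE M21 on GRCm38, in which 55227 of the gene identifiers were found and 260 were not, and 99.0% of the identifiers had identical coordinates. No line of the tables lacked a gene.

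Library totals ran from 48748379 to 65519279 counts. No pair of libraries held identical counts, and the lowest chi-square per degree of freedom over the 49 pairs within groups was 8.44, far above sampling noise. Counting error is small at this depth for all but the lowest genes, and the spread between animals sets the precision.

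Genes with enough counts were kept with edgeR's filterByExpr (minimum count 10), which left 20718. Counts were scaled with TMM factors and tested with edgeR 4.0.16 (R 4.3.3) by the quasi-likelihood F test with group as the only term, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested with a threshold of 0.05. Log2 fold changes are kidney disease minus wild type, with a standard error (SE) from the same fit. CPM values in the text are TMM-scaled, with the SD over animals.

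Before the data were examined, 45 usable lists were fixed, 29 of gene groups and 16 of cell type markers. They were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, and again with a correlation estimated from the data and with fry. The rule for named genes was also fixed then: the 4 genes Col4a3, Col4a4, Col4a5 and Col4a6, the 12 protein-coding genes with the smallest p in each direction, up to 4 members of each list with the smallest p, 12 genes of cardiac load and fuel use, and the gene with the most counts. Cd79a, C1qa, Dcn, Hrc, Frmpd3, Amot and Ttn fall outside the rule and were chosen after their values were seen. Changed genes were counted per chromosome and within 5 Mb of Col4a5 and of Col4a3 with two-sided Fisher exact tests, without Col4a5 and Col4a6 themselves around Col4a5. A list score is the mean log2 CPM of the list's members in a library, and scores were compared by two-sided exact permutation tests over all splits into 7 and 8 animals.

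The pipeline was tested on simulated counts, made from the mean and dispersion of each gene in these libraries, with 230 of 20344 genes changed. Genes varied independently of each other, and changes were placed only in genes with a mean above 1 CPM. The rates below therefore do not cover lower genes or variation that genes share. Of 50 genes simulated at each size, it called 96.0% of those at a log2 change of -1, 78.0% at -0.5, 54.0% at 0.5 and 94.0% at 1, and 5.32% of its 188 calls were false.

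Alternatives fixed in advance were RLE and upper-quartile scaling, DESeq2 1.42.0 with its own filtering of all genes, limma-voom with and without sample weights, robust dispersions, no filter and a filter of at least 1 CPM in 7 libraries, removal of mitochondrial genes, a replicate block, 1 surrogate variable (sva 3.50.0), thinning to equal depth, and leaving out each library. Others were added after seeing the data: the library split described in the report as a covariate or as subsets, the atrial marker score as a covariate, removal of both libraries with the fewest atrial transcripts, and offsets for gene length and GC content.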

Results

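The study asked how the heart changes in mice with chronic kidney disease, and whether its metabolism is altered ahead of hypertrophy. Col4a5 encodes a chain of type IV collagen of the glomerular basement membrane, and its loss causes a progressive nephropathy like Alport syndrome. Gene expression was measured in the left ventricle of 7 kidney disease and 8 wild-type littermate mice, all male and 225 days old.

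Library totals were higher in kidney disease, 58976222 ± 4072528 counts (SD, n = 7) against 52614931 ± 3441329 (SD, n = 8; exact permutation p = 0.0081, adjusted p = 0.020 over 5 library measures). The share of counts from the mitochondrial genome was 11.6% ± 0.800 in kidney disease and 12.9% ± 0.942 in wild type (exact permutation p = 0.017, adjusted p = 0.028). The top 10 genes of a library took 22.0% ± 0.737 and 23.8% ± 0.467 of its counts (exact permutation p = 0.00062, adjusted p = 0.0031). The libraries also split across the groups. Ttn, which encodes the sarcomere protein titin, led 5 libraries (kidney disease 4, 5 and 7 and wild type 6 and 7), and mt-Co1, a mitochondrial gene with 5.1% of all counts, led the other 10. Atrial transcripts varied between animals of both groups, with Nppa at 19.1 to 443 CPM in kidney disease and 12.8 to 346 CPM in wild type.

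Col4a5 (ENSMUSG00000031274, chromosome X, 141475385 to 141689234, GRCm38) was lower in every kidney disease library than in every wild-type library. It had 522 to 1111 counts per library in kidney disease and 2442 to 3620 in wild type, or 13.5 ± 2.97 CPM (SD, n = 7) against 57.0 ± 4.93 CPM (SD, n = 8). Its log2 change was -2.08 (SE 0.11, adjusted p = 3.0e-09). Col4a6 (ENSMUSG00000031273), the neighbouring type IV collagen gene read in the opposite direction, fell further, by 3.73 (SE 0.33, adjusted p = 5.7e-06), with 5 to 30 counts per library in kidney disease and 106 to 355 in wild type. Their annotated exons share no base, and 1308 bases lie between the genes. Col4a3 and Col4a4 on chromosome 1, whose products assemble with the Col4a5 chain in the kidney, had log2 changes of 0.09 (SE 0.10, adjusted p = 0.80) and 0.10 (SE 0.08, adjusted p = 0.72). Col4a5 and Col4a6 were the only 2 of 21 measured genes of the basement membrane list that fell (3 adjusted over the list alone). The list median was -0.05, with adjusted p = 1.4e-06 by camera and adjusted p = 0.24 with an estimated correlation. Because the list holds the mutated gene itself, its test is no separate result.

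**Figure D1:**
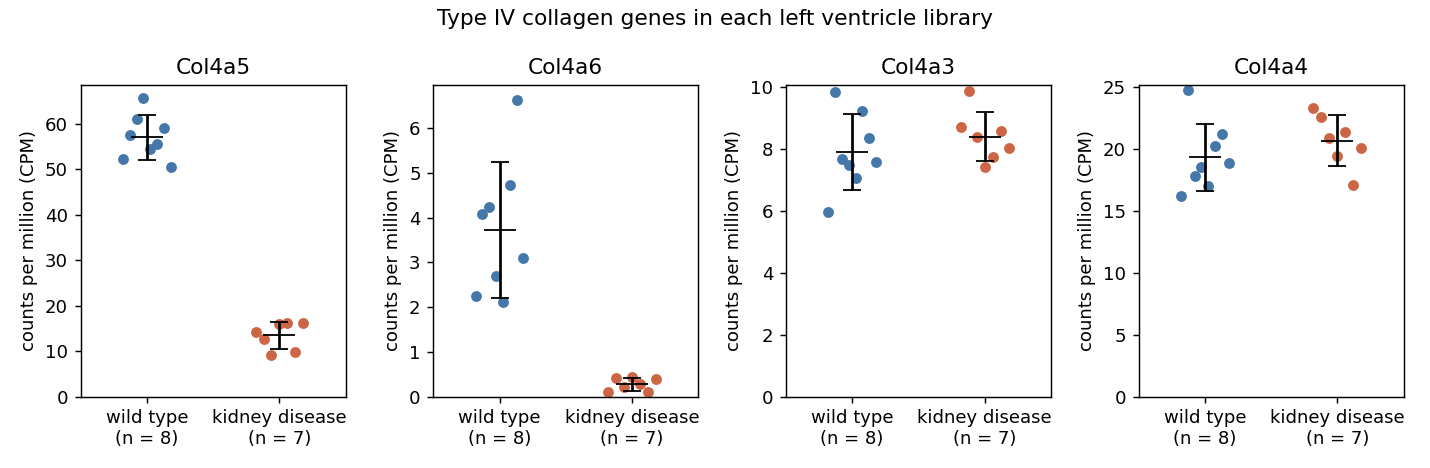
CPM values of 4 type IV collagen genes in each library. Each point is 1 animal and the bars show the mean and SD; Col4a5 lies between 9.19 and 16.2 CPM in kidney disease and between 50.4 and 65.7 CPM in wild type.

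Across the genome, 168 genes rose and 98 fell in kidney disease, of 20718 tested (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted). Most changes were small, with a median absolute log2 change of 0.42 among the 266, and 13 genes rose and 3 fell by more than 2-fold. The genes with the smallest p among those that rose included the Notch target Hey1 (0.69, SE 0.09, adjusted p = 0.0013; 17.4 ± 1.98 against 10.8 ± 1.41 CPM) and the secreted glycoprotein gene Fstl1 (0.47, SE 0.07). Id3 (0.38, SE 0.06), Ccn5 (0.53, SE 0.08), Ctnnal1 (0.37, SE 0.06) and the elongation factor gene Eef1a1 (0.47, SE 0.07) rose as well. Eef1a1 has processed pseudogenes that can share its reads. Mpeg1 (0.55, SE 0.08), Lyz1 (0.80, SE 0.12), Msr1 (0.76, SE 0.12), Pik3ap1 (0.59, SE 0.10) and Fcgr2b (0.48, SE 0.08) were among those that rose too. After the collagen genes, those that fell with the smallest p included the lactate dehydrogenase gene Ldhd (-0.40, SE 0.06, adjusted p = 0.0041), Retsat (-0.52, SE 0.08) and the mitochondrial protein gene Vwa8 (-0.41, SE 0.07). Others that fell included the calcium channel gene Cacna1s (-0.51, SE 0.08), Xirp2 (-0.42, SE 0.07), Fgf1 (-0.34, SE 0.06), the amino acid transporter gene Slc36a2 (-0.47, SE 0.08), Acot2 (-0.33, SE 0.06) and Itgb6 (-0.61, SE 0.11). Each named gene that changed lay on the same side of the wild-type mean in all 7 kidney disease animals. The counts rested on single animals: without wild type 5 there were 67 higher and 30 lower, and without wild type 7 there were 1.17 and 1.96 times as many as with all animals. Within the 10 libraries led by mt-Co1 there were 50 and 36, and within the 5 led by Ttn there were 1 and 2.

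Markers of macrophages and of B cells were higher in kidney disease. Of the 18 measured macrophage and myeloid markers, 12 rose and none fell (18 adjusted over the list alone), with a median log2 change of 0.48. Among them were the protease gene Ctss (0.61, SE 0.10), the growth factor receptor gene Csf1r (0.39, SE 0.07), Lyz2 (0.62, SE 0.11; 128 ± 26.2 against 83.7 ± 10.8 CPM), which shares sequence with Lyz1, Mrc1 (0.35, SE 0.06) and the complement gene C1qa (0.51, SE 0.10). The list passed with adjusted p = 1.1e-36 by camera and adjusted p = 0.0075 with an estimated correlation. Its score was higher in kidney disease by 0.47 (exact permutation p = 0.00031, the smallest these groups allow), by 0.54 within the 10 libraries led by mt-Co1 and by 0.42 within the 5 led by Ttn. Of 10 B cell and plasma cell markers, 5 rose and none fell (9 adjusted over the list alone). Among them were the immunoglobulin genes Igkc (1.45, SE 0.23) and Ighm (0.73, SE 0.13; 11.9 ± 1.87 against 7.19 ± 1.65 CPM), and the B cell surface genes Ms4a1 (1.39, SE 0.31) and Cd79a (1.09, SE 0.25). That list also had adjusted p = 0.0075 with an estimated correlation, and 3 of its genes rose without kidney disease 2, 3, 4, 5 or 6 or wild type 1, 3, 4 or 6. The 9 measured erythroid markers went the other way, with a median of -0.68. None fell over all genes and 9 fell adjusted over the list alone, among them Hba-a1 (-0.69, SE 0.22, adjusted p = 0.15), which shares reads with a near-identical copy. This list had adjusted p = 1.7e-10 by camera and adjusted p = 0.15 with an estimated correlation.

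**Figure D2:**
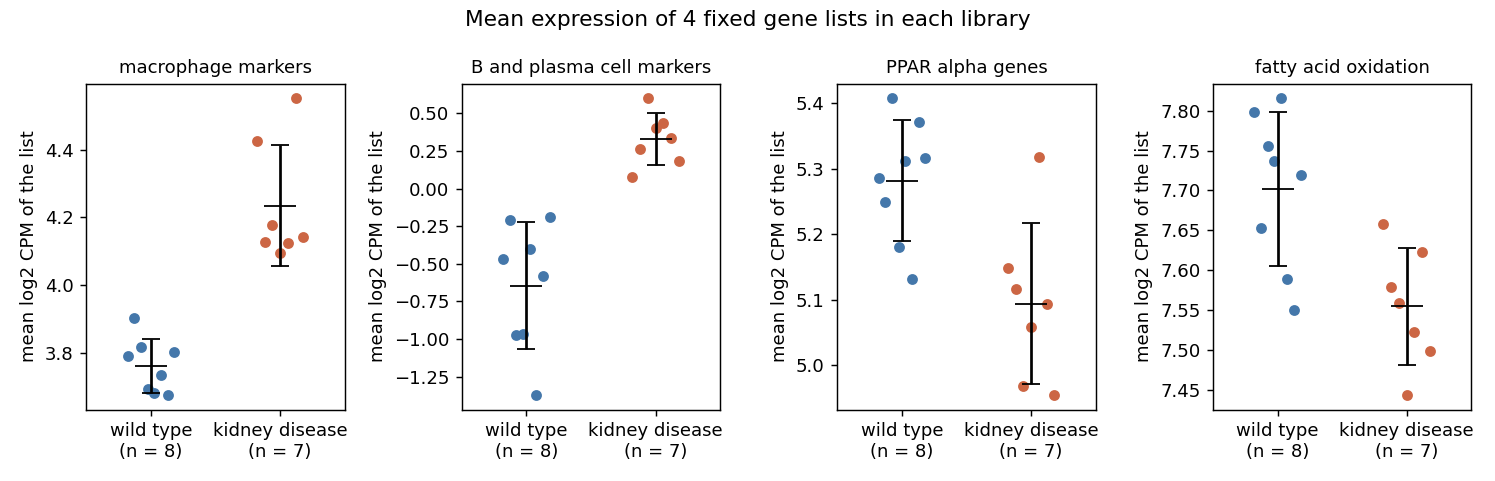
Mean log2 CPM of 4 gene lists in each library. Each point is 1 animal and the bars show the mean and SD; the macrophage scores run from 4.10 to 4.55 in kidney disease and from 3.68 to 3.90 in wild type.

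Genes of the extracellular matrix rose in part. Of 42 measured genes of the extracellular matrix and fibrosis list, 6 rose and none fell (16 adjusted over the list alone), with a median of 0.20. They were Col5a2 (0.35, SE 0.07), the fibrillin gene Fbn1 (0.44, SE 0.09), Col3a1 (0.45, SE 0.11; 351 ± 65.3 against 257 ± 37.4 CPM), Mfap5 (0.51, SE 0.11), Lum (0.25, SE 0.06) and Dcn (0.20, SE 0.05). Its adjusted p was 6.4e-13 by camera, and adjusted p = 0.16 with an estimated correlation. Postn had a log2 change of 0.51 (SE 0.13, adjusted p = 0.056) and Col1a1 of 0.13 (SE 0.12, adjusted p = 0.74). Of 16 fibroblast markers, 5 rose and none fell (6 adjusted over the list alone), with adjusted p = 0.0498 with an estimated correlation. Among them were Dpt (0.30, SE 0.06), Pi16 (0.33, SE 0.07) and Mfap5. Mfap5 belongs to the extracellular matrix and fibrosis list too, so these lists are not independent. In the extracellular matrix and fibrosis list, 1 to 3 genes rose without kidney disease 1, 3, 4 or 5 or wild type 1, 3, 4 or 5. Of the fibroblast markers, 0 to 3 rose without any library other than kidney disease 2 and wild type 2, 7 and 8.

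Genes of fatty acid use fell modestly. In the list of fatty acid uptake and oxidation, 4 of 40 measured genes fell and none rose (11 fell adjusted over the list alone), with a median of -0.14. They were the mitochondrial thioesterase gene Acot2, the carnitine transferase genes Cpt2 (-0.33, SE 0.07; 175 ± 13.6 against 220 ± 20.8 CPM) and Crat (-0.30, SE 0.07), and Hadha (-0.29, SE 0.06), which encodes a subunit of the trifunctional protein of beta-oxidation. Its adjusted p was 1.2e-13 by camera, and adjusted p = 0.16 with an estimated correlation. Of 24 measured PPAR alpha and fasting-responsive genes, 3 fell and none rose (7 fell and 1 rose adjusted over the list alone), Retsat, Acot2 and the glycerol channel gene Aqp7 (-0.38, SE 0.08), with a median of -0.18 and adjusted p = 0.018 with an estimated correlation. Cpt1b (-0.18, SE 0.09, adjusted p = 0.43), Pdk4 (-0.55, SE 0.25, adjusted p = 0.38), Ppargc1a (0.01, SE 0.08, adjusted p = 0.98) and Slc2a4 (-0.04, SE 0.07, adjusted p = 0.90) did not pass. In the fatty acid uptake and oxidation list, 1 or 2 genes fell without kidney disease 3, 4, 5 or 7 or wild type 3, 4 or 5. Adipocyte markers, of a cell type that also expresses Aqp7, had a median of -1.11 with none of 10 past the threshold.

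Few genes of the other energy pathways passed. Of the 13 mitochondrially encoded protein genes, 1 fell, mt-Nd4 (-0.32, SE 0.08, adjusted p = 0.044), and 5 fell adjusted over the list alone, with a median of -0.19, adjusted p = 5.9e-07 by camera and adjusted p = 0.31 with an estimated correlation. Of the mitochondrially encoded protein genes, 1 or 2 fell without kidney disease 1 or wild type 6, 7 or 8, and none without any other library. The gene with the most counts, mt-Co1, changed by -0.16 (SE 0.09, adjusted p = 0.52). None of the 80 nuclear-encoded oxidative phosphorylation genes passed, and their median was 0.06 (adjusted p = 0.21 by camera). With 1 library left out, the camera call or direction of that list differed from the full fit in 8 of 15 fits. None of the 39 genes of glucose uptake and glycolysis passed (median 0.03, adjusted p = 0.80), with a camera direction opposite to that of the median. In the tricarboxylic acid cycle, 0 of 22 genes passed and 2 fell adjusted over the list alone (median -0.07, adjusted p = 0.0012, and adjusted p = 0.56 with an estimated correlation). Of 25 genes of ketone body and branched-chain amino acid catabolism, Ivd fell (-0.27, SE 0.06; 6 adjusted over the list alone; adjusted p = 0.00011, and adjusted p = 0.49 with an estimated correlation). With 1 library left out, Ivd passed only without kidney disease 1 or wild type 2, 6, 7 or 8.

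**Figure D3:**
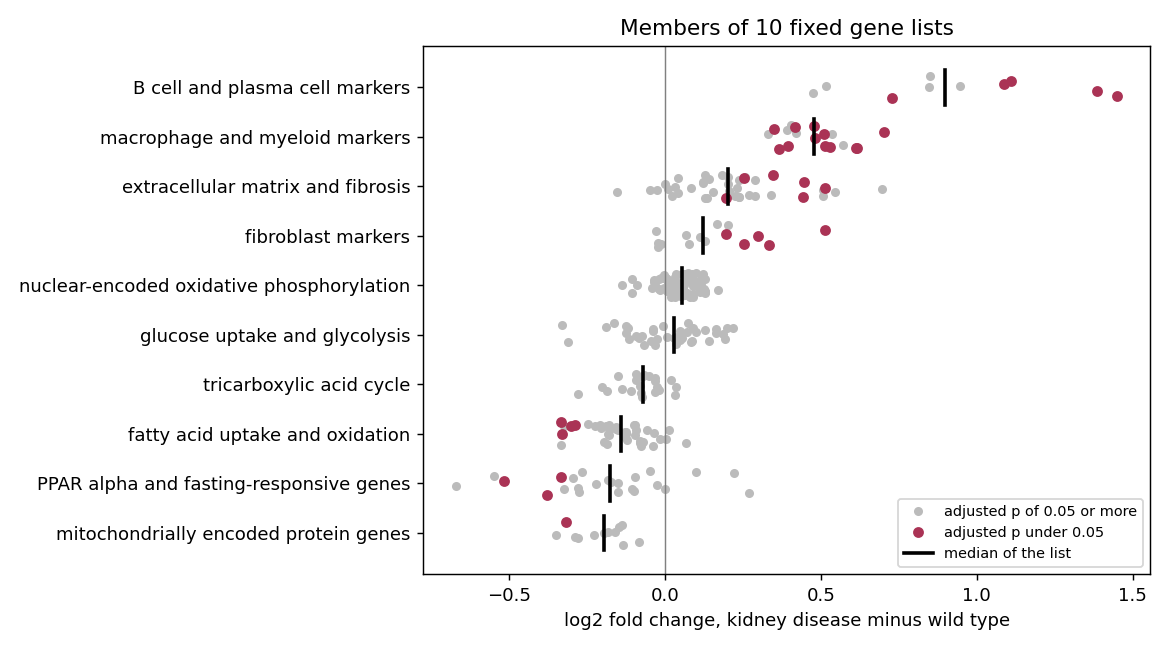
Log2 fold changes of the members of 10 gene lists, kidney disease minus wild type. Each point is 1 gene, coloured where its adjusted p was under 0.05, and the black bar is the median of the list; the medians run from -0.19 for the mitochondrially encoded genes to 0.90 for the B cell and plasma cell markers.

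No gene used as a marker of hypertrophy was called higher. Nppa (0.58, SE 0.51, adjusted p = 0.72), Nppb (0.09, SE 0.24, adjusted p = 0.93), Myh7 (-0.30, SE 0.12, adjusted p = 0.31) and Acta1 (-0.38, SE 0.22, adjusted p = 0.52) did not pass. The SEs of Nppa and Nppb leave room for a rise, and Nppa also varied as an atrial transcript in both groups. In the simulation, 54.0% of randomly chosen genes with a log2 change of 0.5 were called, so such a rise could be missed. A change of 0.5 is below the SE of Nppa, so the rate is lower for a gene that varies as much. Of the 20 natriuretic peptide and hypertrophy-associated genes, Xirp2 fell (3 adjusted over the list alone; median -0.04, adjusted p = 0.024, and adjusted p = 0.20 with an estimated correlation), and 3 of them fell without wild type 7. Of 35 genes of calcium handling and ion channels, 5 fell and none rose (8 adjusted over the list alone; median -0.10). Among them were the potassium channel gene Kcnv2 (-0.41, SE 0.10), the sodium channel subunit gene Scn4b (-0.44, SE 0.10), the kinase gene Camk2b (-0.34, SE 0.08) and Hrc (-0.31, SE 0.07), a calcium-binding protein of the sarcoplasmic reticulum. That list had adjusted p = 2.0e-07 by camera and adjusted p = 0.24 with an estimated correlation, and 0 to 3 genes of calcium handling and ion channels fell without any library other than wild type 7 and 8. The calcium pump gene Atp2a2 changed by -0.13 (SE 0.08, adjusted p = 0.55), and none of 24 sarcomere genes passed (median -0.05, adjusted p = 0.024, and adjusted p = 0.56 with an estimated correlation).

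Few genes of other stress and hormone lists changed. Among 28 inflammatory genes, the adhesion gene Icam1 (0.36, SE 0.08) and the chemokine gene Ccl8 (1.27, SE 0.29) rose (3 rose and 1 fell adjusted over the list alone; adjusted p = 0.00021, and adjusted p = 0.16 with an estimated correlation). Of the inflammatory genes, 0 or 1 rose without any library other than wild type 2 and 7. None of 30 type I interferon genes passed, and 5 rose adjusted over the list alone, with Cxcl10 at 1.12 (SE 0.30, adjusted p = 0.079). The list had adjusted p = 1.8e-06 by camera and adjusted p = 0.38 with an estimated correlation. Single genes rose in the lists of antioxidant genes (Gpx1, 0.37, SE 0.09), of the aryl hydrocarbon receptor and uremic-toxin response (Lgals3, 0.66, SE 0.14), of autophagy (Ctsl, 0.28, SE 0.07), of platelets (Pf4, 0.64, SE 0.11) and of mesothelial cells (Wt1, 0.66, SE 0.14). In the renin-angiotensin-aldosterone list Ednrb rose (0.33, SE 0.07), and in the hypoxia list Ankrd37 rose (0.79, SE 0.16) and P4ha2 fell (-0.27, SE 0.06). Most of these single-gene calls rested on the full set of animals. With 1 library left out, Gpx1 passed only without kidney disease 4 or 5 or wild type 8, and Ctsl only without these or wild type 7. Ednrb passed only without kidney disease 4 or 7 or wild type 2, 7 or 8, and P4ha2 only without kidney disease 4 or wild type 1, 2, 7 or 8. Lgals3 did not pass without kidney disease 3, nor Wt1 without kidney disease 5 or wild type 3 or 5, while Pf4 and Ankrd37 passed in every such fit.

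No member passed over all genes in the lists of core clock genes (median -0.04), immediate early genes (0.11), glucocorticoid-responsive genes (0.03), insulin and FoxO signalling (-0.04), the unfolded protein response (-0.05), heat shock genes (-0.10), mitochondrial biogenesis (-0.06), or the FGF23 and vitamin D axis (0.13). The same held for markers of endothelial cells (0.11), smooth muscle and pericytes (0.02), neutrophils (0.46), T and NK cells (0.23) and atrial cardiomyocytes (0.47). Of these lists, 4 passed by camera and not with an estimated correlation: heat shock genes (3 fell adjusted over the list alone; adjusted p = 2.8e-05 and 0.41), mitochondrial biogenesis (adjusted p = 0.034 and 0.56), endothelial markers (adjusted p = 0.0092 and 0.39) and neutrophil markers (adjusted p = 0.038 and 0.49). With 1 library left out, mitochondrial biogenesis did not pass by camera without kidney disease 2, 4, 5 or 7 or wild type 1, 4 or 5, nor neutrophil markers without kidney disease 4, 6 or 7 or wild type 1, 2, 5 or 6, nor endothelial markers without kidney disease 2. The endothelial score was higher by 0.11 (exact permutation p = 0.024, adjusted p = 0.057 over 14 scores). Over all 45 lists, 12 passed upwards and 13 downwards by camera, the latter including the basement membrane list, which holds Col4a5 itself. Other splits of the animals gave 4 to 28 lists by camera, as described below. With an estimated correlation, 4 passed: macrophage and myeloid markers, B cell and plasma cell markers, fibroblast markers, and PPAR alpha and fasting-responsive genes.

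Changed genes were not concentrated on a chromosome: the smallest p was 0.012, on chromosome 19 (Fisher exact test, adjusted p = 0.20 over 21 chromosomes). Apart from Col4a5 and Col4a6, 2 of 47 tested genes within 5 Mb of Col4a5 changed (Fisher exact p = 0.12), Frmpd3 (-0.80, SE 0.15) and Amot (-0.28, SE 0.07). With 1 library left out, Amot passed only without kidney disease 5 or wild type 2 or 7.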

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

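The tests that weigh explanations in this part were chosen after the results were seen, while the search for single animals far from the rest of their group followed a fixed rule. That search covered 178 groups of values and picked out 11, where chance picks out about 1 in 20, or 8.9. Wild type 7 lay apart from the other wild-type animals with the highest Id3 (42.2 CPM), Myh7 (1355 CPM) and Pdk4 (633 CPM) and the lowest Scn4b (59.1 CPM). Kidney disease 6 had the lowest Xirp2 of its group (710.1 CPM) and the highest Gpx1 (81.0 CPM). Kidney disease 3 had the highest Igkc (7.25 CPM) and Ighm (15.8 CPM). The remaining values were the lowest Ms4a1 in kidney disease 1 (0.567 CPM), the lowest Pi16 in kidney disease 2 (39.1 CPM) and the highest Amot in wild type 3 (34.9 CPM).

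Other splits of the 15 animals into 7 and 8 were fitted in the same way, 100 splits with the real one included. For genes that rose, 1 of 100 splits, the real one, gave as many as 168, and the highest other gave 5. For genes that fell, 1 of 100 gave as many as 98, and the highest other gave 13. Chance is therefore unlikely to give either count, though 100 splits cannot show a share below 1 in 100. For lists past the threshold with a preset correlation, 5 of 100 splits gave as many as the real 25, and the highest other gave 28. The lowest other still gave 4, in a split that called no gene. Chance therefore cannot be excluded for that number. A list call by camera at the preset correlation is weak evidence on its own.

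Macrophage and myeloid markers were higher in kidney disease. A lower share of cardiomyocytes would raise endothelial markers alike, and the macrophage score rose above the endothelial score by 0.36 (exact permutation p = 0.00062). The split of the libraries by their leading transcript leaves a mean difference of 0.50 over both sets (permutation p = 0.00048 within the sets, the smallest they allow). Blood left in the tissue is not excluded. It would raise the markers of neutrophils, B cells, T and NK cells and platelets by at least as large a factor. The summed CPM of these markers rose by 0.53 on the log2 scale, from 44.8 to 64.7 CPM, and that of the macrophage and myeloid markers by 0.47, from 429 to 597 CPM. The difference between them was -0.064 (exact permutation p = 0.56). The blood cell sum holds the B cell markers and Pf4, already seen to rise, so this comparison cannot tell blood from cells of the tissue. The erythroid score went the other way, by a difference of -0.77 (exact permutation p = 0.011), which more blood of the same composition would not give. Whether the composition of the blood differed, in its red cells or their transcripts, was not tested. More blood leukocytes and more macrophages in the ventricle itself could both account for the rise.

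Genes of fatty acid uptake and PPAR alpha were lower in kidney disease. A lower share of cardiomyocytes would lower sarcomere genes alike, and the joint score of these genes fell below the sarcomere score by a difference of -0.10 (exact permutation p = 0.031). Adipocyte markers leaned downwards as well, with a median of -1.11, and Aqp7 is also expressed in adipocytes. With the adipocyte score of each library as a covariate, the difference in the joint score was -0.17 (permutation p = 0.0025 over all splits into 7 and 8) against -0.16 without it, which argues against fewer adipocytes as the whole cause; single genes such as Aqp7 were not tested in this way. Offsets for gene length and GC content left their median at -0.16 against -0.15 without them. The mean difference over both library sets was -0.14 (permutation p = 0.0024 within the sets). A lower use of fatty acids could account for the pattern as a hypothesis, and food intake and time of killing were not tested.

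Col4a6 was lower together with Col4a5. Reads of Col4a5 counted as Col4a6 could lower it at most as far as Col4a5, and it fell further, by a log2 difference of -1.65 (SE 0.35). Flanking genome of another strain around the allele cannot be told apart from an effect of the allele: 2 of 47 other genes within 5 Mb changed, 4.26% against 1.27% elsewhere (Fisher exact p = 0.12), too few genes to decide. An allele that acts on the promoter region shared by both genes stays open and was not tested.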

How the results depend on the processing

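The fits with the library split, the atrial score, without both libraries low in atrial transcripts, and with length and GC offsets were added after the data were seen. Col4a5 and Col4a6 kept their direction and passed in all 33 alternatives, from -2.31 to -1.84 and from -3.95 to -3.56. The counts of genes moved most, and are given here as a multiple of the 168 that rose and the 98 that fell. They were 2.27 and 2.66 with DESeq2, which also replaced the low-count filter by its own, so that the 2 changes cannot be told apart. They were 1.55 and 2.29 with limma-voom sample weights, 3.23 and 2.96 with 1 surrogate variable, and 1.99 and 1.92 with the library split as a covariate. They were 0.298 and 0.367 in the 10 libraries led by mt-Co1, 0.00595 and 0.0204 in the 5 led by Ttn, 2.14 and 2.14 with the atrial score, and 0.351 and 0.327 without both libraries low in atrial transcripts. For genes that fell, the multiple was 0.663 without a filter and 1.57 with the stricter filter. Leaving out each library gave 0.399 to 1.17 for genes that rose and 0.306 to 1.96 for those that fell. Every library moved a count by more than 1.5 times except, for the higher genes, kidney disease 2 and 7 and wild type 2, 7 and 8, and for the lower genes, wild type 2 and 8. The subsets hold fewer samples, and the cause of the other moves was not tested.

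The labels do not say that replicate numbers pair the animals. The correlations of same-numbered deviations ran from -0.20 to 0.42, and 2 of 7 kidney disease animals correlated best with their own number. These values show no strong pairing over all numbers and cannot exclude a weaker shared effect. With the replicate number as a block, which leaves out wild type 8, the multiples were 0.393 and 0.510.

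Median log2 changes are given here for lists, whose direction is that of camera. Nuclear-encoded oxidative phosphorylation turned downwards with limma-voom sample weights (-0.058) and without both libraries low in atrial transcripts (-0.025). It passed upwards without a filter (0.063), with the replicate block (0.077), with 1 surrogate variable (0.10), with the library split (0.11) and with the atrial score (0.082). Leaving out a library gave -0.047 (kidney disease 6) to 0.088, and the camera call or direction differed from the full fit in 8 of these 15 fits. Glucose uptake and glycolysis passed downwards with sample weights (-0.039). It turned upwards without a filter (0.039), with the replicate block (0.049), 1 surrogate variable (0.046), the library split (0.039), the atrial score (0.057) and fry (adjusted p = 0.996). Leaving out a library gave -0.023 to 0.053, and the camera call or direction of glucose uptake and glycolysis differed in 6 of these 15 fits. The tricarboxylic acid cycle no longer passed with 1 surrogate variable (-0.035), the library split (-0.030), an estimated correlation (adjusted p = 0.56) or fry (adjusted p = 0.37), and turned to 0.023 in the 5 libraries led by Ttn. Natriuretic peptide and hypertrophy-associated genes no longer passed in those 5 libraries (0.0099), without kidney disease 1 or without kidney disease 2, with an estimated correlation (adjusted p = 0.20) or fry (adjusted p = 0.080), and leaving out a library gave -0.069 to -0.0077. An estimated correlation ended the calls of the extracellular matrix and fibrosis list (adjusted p = 0.16), of fatty acid uptake and oxidation (adjusted p = 0.16) and of the mitochondrially encoded genes (adjusted p = 0.31; fry adjusted p = 0.14). By fry, the extracellular matrix and fibrosis list (adjusted p = 0.040) and fatty acid uptake and oxidation (adjusted p = 0.037) passed. So did inflammatory genes (fry adjusted p = 0.037) and erythroid markers (fry adjusted p = 0.043). Macrophage and myeloid markers and the PPAR alpha list kept their call by camera when any 1 library was left out, with medians of 0.41 to 0.52 and -0.21 to -0.15.

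Among values that had not passed, Nppb turned to -0.011 with limma-voom, -0.22 with sample weights, -0.13 without both libraries low in atrial transcripts and -0.18 without kidney disease 6, and leaving out a library gave at most 0.22. Ppargc1a turned to -0.029 with the replicate block, -0.0021 with 1 surrogate variable, -0.00031 with the library split and -0.0099 with the atrial score, and leaving out a library gave -0.041 to 0.049. Slc2a4 turned to 0.00066 with 1 surrogate variable and 0.0049 with the library split, and Ttn to 0.037 with length and GC offsets. For lists, the direction that turned is that of camera, and the printed median can keep its sign. Creatine and purine metabolism, with a median of -0.041 in the main fit, is such a list. It turned at medians of -0.015, -0.019 and -0.028 with 1 surrogate variable, the library split and the atrial score. Conduction system markers turned in the same fits, to -0.047, -0.040 and -0.073. Without single libraries the conduction markers ran from -0.058 to 0.26. The unfolded protein response turned to -0.011 with 1 surrogate variable and -0.013 with the library split, and leaving out a library gave -0.091 to 0.013. Atrial markers turned to -0.064 with the atrial score. Without both libraries low in atrial transcripts, immediate early genes turned to 0.0014 and glucocorticoid genes to -0.011. Lists that had passed by camera with all animals turned as well in the 5 libraries led by Ttn. They were mitochondrial biogenesis (0.018), sarcomere (0.0066), type I interferon (-0.022), cell cycle (-0.053), endothelial markers (-0.023) and adipocyte markers (0.22).

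Of the 15 fits that each leave out 1 library, the gene did not pass in 13 for Dcn, in 12 for Lum, Col3a1, Scn4b, Hrc, Gpx1 and Amot, and in 11 for Ms4a1, mt-Nd4 and Ctsl. It did not pass in 10 for Cd79a, Pi16, Kcnv2, Ivd, Ccl8, P4ha2 and Ednrb, in 9 for Hadha and Camk2b, and in 8 for Crat and Icam1. The number was 6 for Fbn1, 5 for Aqp7, 4 for Dpt, Mfap5 and Cpt2, 3 for Wt1 and 1 for Lgals3. By camera, mitochondrial biogenesis, autophagy and neutrophil markers each did not pass in 7 of these fits, sarcomere and antioxidant genes in 5, the aryl hydrocarbon receptor list in 3, adipocyte markers and the hypertrophy-associated genes in 2, and endothelial markers in 1.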

Other observations

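These values were looked at after the results were seen. Genes for cytoplasmic ribosomal proteins leaned upwards together: 74 of 77 measured had a positive log2 change, with a median of 0.21 and a range from -0.09 to 0.35, though none passed the threshold over all genes. Their score did not differ between the groups over all animals (difference 0.19, exact permutation p = 0.13), and within the library sets the mean difference was 0.25 (permutation p = 0.0048). The translation elongation factor gene Eef1a1, which did rise, is part of the same machinery.

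Cell cycle genes showed positive log2 changes in 20 of 22 members with a median of 0.45, and none passed over all genes (adjusted p = 0.00011 by camera, and adjusted p = 0.43 with an estimated correlation). The median was 0.21 without kidney disease 6. Adipocyte markers had a median of -1.11 over 10 measured genes, with none past the threshold and 3 that fell adjusted over the list alone (adjusted p = 0.0059 by camera, and adjusted p = 0.49 with an estimated correlation). This rested on 2 wild-type animals: the median was -0.61 without wild type 2 and -0.77 without wild type 1, and the list did not pass by camera without either (adjusted p = 0.084 and adjusted p = 0.059). The genes that fell were longer than those that rose, with median exonic lengths of 5517 and 3240 bases, against 3348 for all genes tested. Over all genes the log2 change was only weakly related to length (Spearman rho -0.062).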
